A study of Mus musculus with 3 samples.

How the data were processed

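MeDIP-seq libraries from epididymal fat of male C57BL/6J mice on the normal, high-fat and folic acid supplemented high-fat diets were analysed, 1 per diet, with groups taken from the labels. Whether a library came from 1 animal or a pool is not given in the sources used here. DNA was extracted with a column kit and libraries were made with an Illumina kit, per the labels' protocols. The deposited files are peak lists, 1 per library, in build mm10 per the submitters' processing notes. Peak names carry the prefix of the MACS peak caller, and its version, settings and control, the aligner, the read depth and any handling of duplicate reads are not given in the sources used here. Each peak carries the authors' own score, which is at least 50 in every list. Its scale is not stated, so the score was used to rank and filter peaks within a list, and counts above a given score are comparable between lists only if they share a scale. Peaks were called per library by the authors, so a peak missing from a list means that no region passed the caller's threshold there, which depends on depth as well as on methylation.

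Overlap of peaks with each other and with gene-end windows required 1 bp, while a peak's feature was set by its midpoint. Shuffled values are means over 10 placements of each library's peaks within their chromosomes. Gene positions came from a RefSeq gene table of assembly GRCm38.p6, which is the assembly of mm10. That table gives no strand, exons or sequence. The plan had named promoters at the 5′ end, so windows were placed instead at both ends of each gene record, from 2000 bp outside to 500 bp inside, and a gene was called marked when a peak overlapped either window. A marked gene end can therefore be the start or the end of the gene. For the same reason random lists were matched on gene length in 20 bins and not on CpG density, shuffling did not avoid assembly gaps, features were gene end, gene record and between genes, and CpG content, CpG islands and start sites of single transcripts were not analysed here.

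Among 49939 gene records on 21 chromosomes, 21883 were protein-coding. The 19 gene lists held 913 symbols, of which 911 matched the table; only protein-coding members were counted, which removed 11 non-coding or unmatched imprinted genes. Counts were set beside 10000 random lists, and the percentile describes these libraries and is no p-value. The gene lists, the alternative settings other than those named next and the naming rule below were fixed before the data were examined. The windows at both gene ends, the 5000 bp naming rule, the ratios of peak numbers in gene records and the members on autosomes were chosen after the files were seen. The naming rule took, for each direction of HFD against ND and FAD against HFD, the 6 genes with the highest score among those with no gene-end peak in the other library, 3 for FAD against ND, up to 3 members of each list per direction, the 5 highest for each of the patterns over 3 libraries, all one-carbon and cAMP genes that differed, and the 3 highest regions found in 1 library only. Symbols of the form Gm with digits or ending in Rik were passed over, and some genes that the rule names are not reported here. Most top names by this rule were shifted peak edges. The same ranking among genes with no peak of the other library within 5000 bp of the windows was therefore added after the data were seen. An exception was the genes marked in ND and FAD only, where the fixed rule averaged the ranks in both lists. The added rule ordered these by ND score alone.

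Genes by pattern of presence over the 3 libraries were compared with a conditional model that gives each gene its own propensity and each library its own detection level. In 200 simulated data sets of 21883 genes without a diet effect, 4 lay above all of their own simulated sets. With 200 genes set at random to HFD only or to ND and FAD only, 199 did. These data were drawn from the form of model that was fitted, and a change in 1 direction only was not simulated. A first run had used 20 data sets, of which 2 without an effect lay above, and the number was raised to measure that rate. The overlap code gave the same call as bedtools for all 394066 peaks compared. Intervals are Wilson 95% intervals. Alternatives were the 50% of peaks with the highest scores, equal-length lists of 95501 peaks, autosomes, a reciprocal overlap of 50%, joining of peaks within 500 bp, windows of 1000 bp on each side, peak midpoints, absence within 5000 bp, and gene bodies. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9 were used.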

Results

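DNA methylation in epididymal fat was profiled by methylated DNA immunoprecipitation sequencing (MeDIP-seq), in which an antibody enriches methylated fragments and enriched regions are called as peaks. Male C57BL/6J mice, 6 weeks old at the start, were kept for 10 weeks on a normal diet (ND) with 10% of its energy from fat, on a high-fat diet (HFD) with 60%, or on the high-fat diet with folic acid at 20 μg/mL in their water (FAD). There was 1 library per diet, so every difference below lies between 3 libraries and has no replicate check. The ND list held 101532 peaks over 59.7 Mb, the HFD list 135124 peaks over 89.1 Mb and the FAD list 95501 peaks over 49.2 Mb, with median widths of 507, 587 and 447 bp. Read depth is unknown from these lists. Wilson 95% intervals given below cover counting error over peaks only.

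Lists of genes known to carry promoter methylation in somatic tissue held more genes with a peak at either gene end than random lists in all 3 libraries. Of 61 germline genes, 37 had a peak at a gene end in ND, 40 in HFD and 32 in FAD, where random lists of genes of like length held a median of 14, 19 and 13. The 32 members marked in every library included the synaptonemal complex genes Sycp1, Sycp2 and Sycp3, the RNA helicase gene Ddx4 and Dazl. Of 50 imprinted genes, 23, 27 and 21 were marked in ND, HFD and FAD, and 20 of them, among them Peg3, Peg10, Mest, Nnat and Plagl1, in all 3. Housekeeping genes with CpG island promoters were marked less often than random lists: 7, 12 and 4 of 55, against random medians of 14, 18 and 12. The HFD count lay inside the random range (percentile 3.82). Among 21883 protein-coding genes, 4928 (22.5%) had a gene-end peak in ND, 6663 (30.4%) in HFD and 4352 (19.9%) in FAD.

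**Figure D1:**
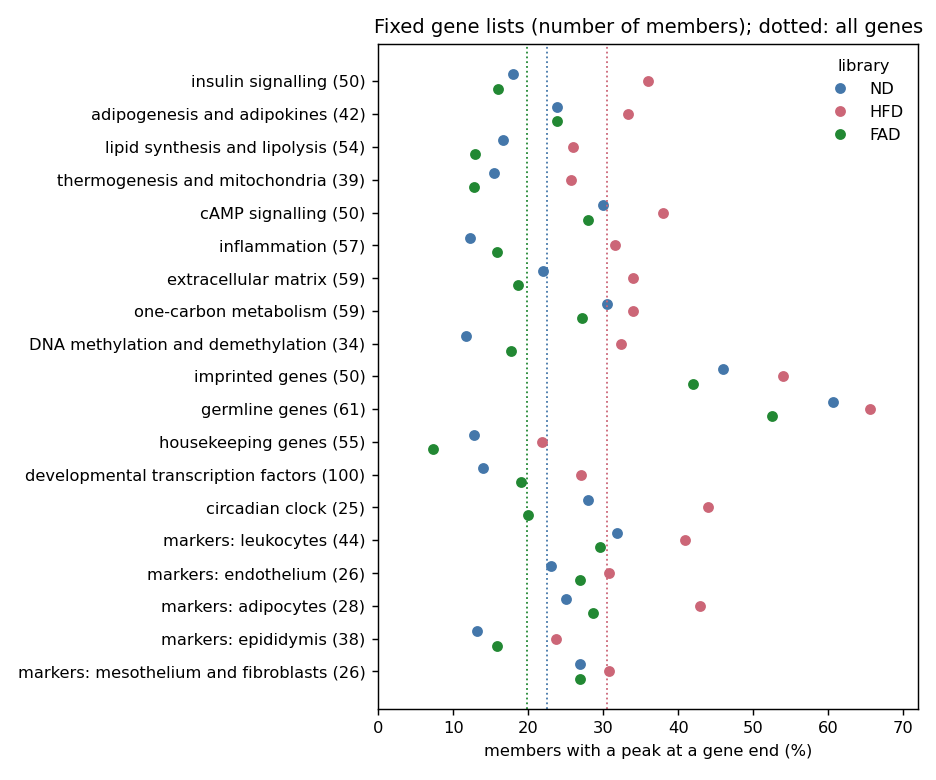
Share of members with a peak at a gene end (x axis, percent) for 19 gene lists (y axis, number of members in parentheses) in the ND, HFD and FAD libraries, with dotted lines at the share of all protein-coding genes. Germline and imprinted genes lie to the right of the lines in all 3 libraries, and the HFD point is the rightmost in every list.

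Strongly enriched regions were common to the 3 diets. In the highest-scoring decile of each list, at least 99.6% of peaks overlapped a peak of any other library, while in the lowest decile the share ran from 21.9% of HFD peaks in FAD to 57.6% of FAD peaks in HFD. Over whole lists, 83.4% of ND peaks (83.1 to 83.6%) overlapped an HFD peak and 61.9% of HFD peaks (61.6 to 62.1%) an ND peak. FAD peaks overlapped HFD in 84.5% (84.2 to 84.7%) and ND in 74.4% (74.1 to 74.6%), HFD peaks overlapped FAD in 58.6% (58.3 to 58.8%), and ND peaks overlapped FAD in 69.4% (69.1 to 69.7%). Shuffled peaks overlapped in 4.01 to 6.43%. With the 95501 top-scoring peaks of each library, the 6 shares came to between 71.8 and 74.2%.

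**Figure D2:**
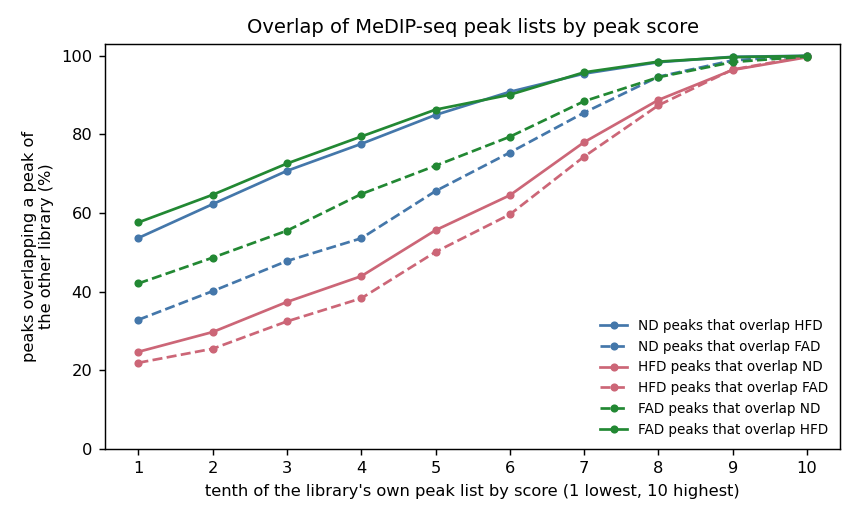
Percent of peaks that overlap a peak of another library (y axis) by decile of the library's own list ordered by score (x axis), 1 line per directed pair of libraries. All lines reach at least 99.6% in the highest decile and spread from 21.9 to 57.6% in the lowest.

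Peaks found in 1 library only were weak. They numbered 12738 in ND (12.5% of its list), 38062 in HFD (28.2%) and 10627 in FAD (11.1%), and of these 5, 71 and 3 had a score of 200 or more. The highest-scoring HFD-only region lay at chromosome 15, 30956622 to 30956929 (score 312), in Ctnnd2, which encodes delta-catenin, and another at chromosome 16, 4890675 to 4890960 (score 278), in the ubiquitin ligase gene Mgrn1. The third, at chromosome 11, 4614379 to 4614701 (score 278), lay outside any gene record. In FAD the highest lay at chromosome 1, 16008175 to 16008344 (score 267), and in ND at chromosome 7, 15044676 to 15044941 (score 219), both between genes. All of these regions were narrow. Those of HFD spanned 308, 286 and 323 bp, where the narrowest decile of HFD peaks ended at 367 bp. Those of FAD and ND spanned 170 and 266 bp, against 286 and 323 bp for that decile.

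The first comparison, HFD with ND, asks where the methylated regions of fat differ with dietary fat. Mtnr1b, which encodes a melatonin receptor, had an HFD peak across its gene end (chromosome 9, 15874266 to 15875160, score 303) and the nearest ND peak 24575 bp away. Actr10, a dynactin subunit gene, Pigf, a gene of GPI anchor synthesis, Gykl1, Stkld1 and Tstd3 followed with scores of 259, 256, 208, 197 and 194. In the other direction, Olfr1261, an olfactory receptor gene, had an ND peak with score 168 and the nearest HFD peak 21212 bp away. The calcium-binding protein gene S100a4 (149), the ribosomal protein gene Rps6 (146), Tmem150a (141), Ifi214 (124) and Zfp960 (124) came next. These 12 genes are the highest-scoring ones with no peak of the other library within 5000 bp of the gene-end windows, a rule chosen after the data were seen. Some of their peaks were narrow. Those of Olfr1261, Rps6, Ifi214 and Zfp960 spanned 302, 281, 244 and 227 bp, where the narrowest decile of ND peaks ended at 323 bp. The Pigf peak spanned 280 bp, against 367 bp for that decile in HFD. The rest were wider than these limits. Narrow peaks are weighed at the end for peaks found in 1 library only.

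In all, 2312 genes had a gene-end peak in HFD and none in ND, and 577 the reverse. With no peak allowed within 5000 bp of the windows the counts were 779 and 118, and with lists of equal length 1370 and 1000. The genes with the highest scores by the rule fixed before the data were examined were Eppk1 (1101), Disp1 (765), Pisd (707), Dennd1c with Tubb4a (705), Cox6b2 (593) and Tenm2 (553) in HFD, and Tmem125 (3100), Cast (721), Zfp775 (379), P2ry6 (260), Top1mt (256) and Mppe1 (245) in ND. At all 7 and all 6 of these genes the peak overlapped a peak of the other library that stopped short of the window, so they mark shifted peak edges and no absent peak. Of all 2312 and 577 genes, this held for 221 (9.56%) and 50 (8.67%).

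Inflammation genes had the highest percentile of the lists for peaks in HFD and not in ND. Of 57 members, 13 were marked in HFD and not in ND, against a random median of 6, at percentile 99.5 of 10000 random lists, and 2, Nos2 and Trem2, were marked the other way. The difference came from a low ND count: 7 members were marked in ND against a random median of 14 (percentile 1.07), while the 18 marked in HFD lay at percentile 42.0. Ccl3 and Ccl4 are among the 13. Their gene records overlap and each held 1 HFD peak, so both may rest on 1 region. Random lists were not matched on such neighbours. Nlrp3, a sensor of the inflammasome, had an HFD peak with score 199 and the nearest ND peak 8546 bp away, and Mapk8, which encodes the stress kinase JNK1, a peak with score 167 and the nearest ND peak 13652 bp away. Cxcl12 (180) was an edge case, with its peak overlapping an ND peak. Of 13 members, 4 (Ccl5, Cxcl5, Lgals3 and Mapk8) had no ND peak within 5000 bp of a window. Among 76 pairs of a list and a direction of HFD against ND or FAD against HFD, this was the 1 pair beyond the central 95% of random lists, where the nominal chance number is 3.8. That number is too high where small counts cannot reach the lower tail. For peaks in ND and not in HFD, 0 insulin signalling genes still lay at percentile 12.0. For peaks in FAD and not in HFD, 0 inflammation genes lay at percentile 15.4. Among the 50% of peaks with the highest scores the inflammation count in HFD and not in ND was 4, at percentile 47.6, with gene bodies it was 8, at percentile 79.8, and with equal-length lists 8, at percentile 97.7.

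Insulin signalling genes were marked in HFD and not in ND at 9 of 50 members (percentile 93.6) and at no member in reverse, but with equal-length lists the counts were 3 and 2 (percentiles 48.4 and 45.7). Igf1r, the receptor gene of insulin-like growth factor 1, and Grb10, an adaptor gene, had no ND peak within 5000 bp of a window, whereas the HFD peaks of Gsk3a (548), Trib3 (206) and Shc1 (201) overlapped ND peaks. Within their records and 2000 bp on each side, Igf1r and Grb10 held 27 and 3 ND peaks, and 36 and 6 HFD peaks. Of the 42 adipogenesis and adipokine genes, Retn, which encodes resistin (chromosome 8, 3654696 to 3655067, score 182, nearest ND peak 14925 bp away), Srebf1 (118) and Plin1, the perilipin gene (108), were among 5 marked in HFD and not in ND. Ebf2, a transcription factor gene of brown adipocyte identity, was the 1 member marked in ND and not in HFD (score 79.6, nearest HFD peak 12265 bp away). The count of 5 lay at percentile 59.7. The Srebf1 peak spanned 310 bp, where the narrowest decile of HFD peaks ended at 367 bp.

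Lipid and thermogenic genes did not stand apart at gene ends. Of 54 genes of lipid synthesis and lipolysis, 7 were marked in HFD and not in ND (percentile 63.6), among them Mogat2 (215, overlapping an ND peak), Srebf2 (76.8) and Scd2 (76.5), and 2, Acaca (54.5) and Acadvl (51.6), in reverse. With gene bodies included no lipid gene was marked in HFD and not in ND, below the random median of 5 (percentile 0.295). Of 39 thermogenic and mitochondrial genes, 4 were marked in HFD and not in ND (percentile 48.8), with Adrb3, the beta-3 adrenergic receptor gene (101), Cox7a1 (75.2) and Slc25a20 (72.7) at the top. Extracellular matrix genes gave 8 of 59 (percentile 72.4; Mmp19, 125), with Lum, the lumican gene (75.5), in reverse. The peaks of Scd2 and Adrb3 spanned 359 and 294 bp, where the narrowest decile of HFD peaks ended at 367 bp. That of Lum spanned 321 bp, against 323 bp for that decile in ND. DNA methylation and demethylation genes gave 7 of 34 (percentile 94.5; Mbd2, 140, overlapping an ND peak, Apobec2, 91.9, and Mbd1, 83.2), and with equal-length lists 6 of 34 (percentile 98.5).

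Genes of one-carbon metabolism, the pathway that uses folate, were marked in HFD and not in ND at 5 of 59 members (Chdh, 118, Bhmt2, 99.4, Mmab, 92.4, Folr1 and Fpgs), at percentile 24.3. The reverse held for Slc25a32 (62.5), Mthfsl (60.1) and Cbs (59.1), the gene of cystathionine beta-synthase. Only Folr1 of the first group and Mthfsl of the second had no peak of the other library within 5000 bp of a window. Of 50 cAMP signalling genes, 5 (Creb3l1, 278, Pde10a, 126, Crtc1, 94.5, Adcy6 and Crtc3) were marked in HFD and not in ND, at percentile 45.4, and Adrb1, the beta-1 adrenergic receptor gene (56.8), in reverse. All 5 had an ND peak within 5000 bp of a window, and the nearest ND peak lay 605 bp from the Creb3l1 peak. Developmental transcription factors gave 15 of 100 (percentile 92.5), and 8 of them, Gata4, Hoxc9, Hoxd10, Irx1, Lhx2, Nkx2-2, Pax3 and Pax8, had no ND peak within 5000 bp. Only 14 of the 100 were marked in ND (percentile 0.305), and the count of 15 fell to 7 with equal-length lists, with the 50% of peaks that scored highest and with gene bodies (percentiles 60.1, 43.2 and 12.4). Clock genes gave 5 of 25 (percentile 90.4; Csnk1e, 131, and Cry2, 118), all with an ND peak within 5000 bp of a window. Counts for imprinted, germline and housekeeping genes were 5 of 50, 5 of 61 and 6 of 55.

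Markers of cell types that fat can hold were read in the same way. Adipocyte markers were marked in HFD and not in ND at 5 of 28 genes (percentile 86.3), leukocyte markers at 6 of 44 (percentile 72.8; Cd2, 100.4, and Runx3, 99.3), endothelial markers at 4 of 26 (percentile 75.5; Tek, 85.6), epididymal markers at 5 of 38 (percentile 73.6; Defb42, 96.2) and markers of mesothelium and fibroblasts at 1 of 26 (percentile 12.5; Pdgfrb, 91.7).

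The second comparison, FAD with HFD, asks where folic acid goes with a different set of methylated regions on the same diet. Slc12a3, the gene of a sodium-chloride cotransporter, had an HFD peak across its gene end (chromosome 8, 94329051 to 94329609, score 340) and the nearest FAD peak 7766 bp away. Actr10 (259), Yae1d1 (245), Naaladl2 (235), Tmem225 (235) and the major histocompatibility complex gene H2-Eb2 (224) followed, and for H2-Eb2 the nearest FAD peak lay 76398 bp away. Tyr, which encodes tyrosinase, the first enzyme of melanin synthesis, led the other direction with an FAD peak (score 185) and the nearest HFD peak 7200 bp away. The homeobox genes Rhox4b (160) and Rhox4c (119), with Morf4l1b (143), Olfr1057 (119) and Skint7 (102.7), came next. The 5000 bp rule again set these 12 names. Several of the peaks were narrow here too. Those of Yae1d1, Naaladl2, Tmem225 and H2-Eb2 spanned 340, 354, 346 and 351 bp, where the narrowest decile of HFD peaks ended at 367 bp. Those of Rhox4c and Olfr1057 spanned 239 and 223 bp, against 286 bp for that decile in FAD. The rest were wider than these limits.

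In all, 435 genes had a gene-end peak in FAD and none in HFD, and 2746 the reverse. With no peak allowed within 5000 bp the counts were 100 and 1009, and with equal-length lists 867 and 1556. The rule fixed before the data were examined named Cast (604), Fos (275), Hat1 (217), Tyr (185), Olfr1459 (181) and Zbp1 (170) in FAD, and Eppk1 (1101), Gtf2ird2 (817), Zfp42 (780), Disp1 (765), Pisd (707) and Slc2a2, a glucose transporter gene (624), in HFD. The peak overlapped a peak of the other library at 4 of the 6 FAD genes, all but Tyr and Olfr1459, and at all 6 HFD genes.

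Insulin signalling genes were marked in HFD and not in FAD at 11 of 50 members (percentile 96.0), and 9 of these were also unmarked in ND. With equal-length lists the count was 4 (percentile 57.2), against 2 in reverse, with the 50% of peaks that scored highest it was 4, and with gene bodies 3. Igf1r and Trip10 had no FAD peak within 5000 bp of a window, while the peaks of Gsk3a, Trib3 and Shc1 overlapped FAD peaks. With 2000 bp on each side, the records of Igf1r and Trip10 held 23 and 3 FAD peaks, and 36 and 6 HFD peaks. Irs1, the gene of insulin receptor substrate 1, was the 1 member marked in FAD and not in HFD (chromosome 1, 82233230 to 82233476, score 98.0, nearest HFD peak 10338 bp away). That peak spanned 247 bp, where the narrowest decile of FAD peaks ended at 286 bp. With 2000 bp on each side, the Irs1 record held 1 HFD peak and 2 FAD peaks. Among adipogenesis and adipokine genes, Adipor2, an adiponectin receptor gene (145, nearest FAD peak 11985 bp away), Srebf1 and Plin1 were among 5 of 42 marked in HFD and not in FAD (percentile 41.8). The Adipor2 and Srebf1 peaks spanned 338 and 310 bp, where the narrowest decile of HFD peaks ended at 367 bp. Lep, the leptin gene, carried a weak FAD peak across its gene end (score 56.1, nearest HFD peak 2085 bp away).

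Lpl, the lipoprotein lipase gene (127, nearest FAD peak 14720 bp away), and Ucp1, which encodes the uncoupling protein of brown fat (116, nearest FAD peak 14846 bp away), were marked in ND and HFD and not in FAD. Their lists gave 8 of 54 (percentile 61.1) and 5 of 39 (percentile 51.7) marked in HFD and not in FAD, and Mlxipl (71.3) was the 1 lipid gene marked in FAD and not in HFD. Inflammation genes gave 9 of 57 (percentile 72.6; Nlrp3, Cxcl12, overlapping an FAD peak, and Tnfrsf1a, 115) and no member in reverse. Extracellular matrix genes gave 11 of 59 (percentile 88.6), where the peaks of Col6a2 (332), Fbn1 (185) and Tgfb3 (163) overlapped FAD peaks, and Eln, the elastin gene (90.5), and Timp2 (53.1) in reverse.

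Genes of one-carbon metabolism were marked in HFD and not in FAD at 6 of 59 members (percentile 24.2). The folate transporter gene Slc46a1 (153), Aldh1l1 (126, nearest FAD peak 28758 bp away) and Amt of the glycine cleavage system (88.8, nearest FAD peak 24677 bp away) led, and Folr1 and Fpgs were also among them. Aldh1l1 and Amt alone of the 6 had no FAD peak within 5000 bp of a window. In reverse stood Gldc, also of the glycine cleavage system (64.6), and Mtr, the methionine synthase gene (54.8). In cAMP signalling the count was 6 of 50 (percentile 45.5): Rapgef4 (182) and Gnas (179), whose peaks overlapped FAD peaks, Gipr (85.3), Adcy6, Adcy9 and Crtc3, with Pde4d (52.3) in reverse. All 6 had an FAD peak within 5000 bp of a window. Each of the 3 libraries marked 11 one-carbon genes in common, among them Slc19a1, the reduced folate carrier gene, and 10 cAMP genes.

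Developmental transcription factors marked in FAD and not in HFD numbered 5 of 100, namely Hoxc6 (89.3), Hoxc11 (77.7), Wt1 (61.3), Hoxc10 and Pax6, at percentile 97.1 and inside the central 95% of random lists, against 13 in reverse (percentile 52.1). The count of 5 fell to 1 with the 50% of peaks that scored highest (percentile 41.0) and to 3 with gene bodies (percentile 81.1). The Hoxc11 peak spanned 261 bp, where the narrowest decile of FAD peaks ended at 286 bp. DNA methylation genes gave 5 of 34 in HFD and not in FAD (percentile 60.7; Mbd2, Mbd1 and Dnmt3l), and none in reverse. Clock genes gave 6 of 25 (percentile 93.6; Nfil3, 291, overlapping an FAD peak, Per3, 134, and Cry2), all with an FAD peak within 5000 bp of a window. Imprinted genes gave 7 of 50, germline genes 8 of 61, with Fthl17a (189) 240740 bp from the nearest FAD peak, and housekeeping genes 9 of 55. Adipocyte, leukocyte, endothelial, epididymal and mesothelial or fibroblast markers gave 5 of 28, 6 of 44, 3 of 26, 4 of 38 and 2 of 26, at percentiles 76.5, 56.1, 42.6, 38.3 and 22.3. Epididymal markers marked in FAD and not in HFD numbered 1 of 38 (percentile 65.5), or 3 with the 50% of peaks that scored highest (percentile 99.3).

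The third comparison, FAD with ND, sets the supplemented high-fat diet against the normal diet. Fermt3, the kindlin-3 gene of blood cells, shared with Stip1 an FAD peak (score 188) that lay 30915 bp from the nearest ND peak, and Gimap9 (161) and Defb47 (154) followed. The Fermt3 peak spanned 231 bp, where the narrowest decile of FAD peaks ended at 286 bp. In ND and not in FAD stood P2ry6 (260), Gpr151 (255) and Uts2, the urotensin 2 gene (228), again by the 5000 bp rule. The Uts2 peak is also the ND peak of the clock gene Per3, whose record overlaps that of Uts2, so the 2 names share 1 region. It spanned 269 bp, where the narrowest decile of ND peaks ended at 323 bp. In all, 924 genes were marked in FAD and not in ND and 1500 the reverse, or 303 and 527 with no peak allowed within 5000 bp. Developmental transcription factors gave 9 of 100 in FAD and not in ND (percentile 98.4), a comparison outside the 76 pairs counted above. The low ND count enters here too, with 14 of 100 against a random median of 25, while the 19 marked in FAD lay at percentile 23.1. The percentile was 96.8 with equal-length lists, 57.9 with the 50% of peaks that scored highest (3 genes) and 41.3 with gene bodies (4 genes). The highest scores by the fixed rule belonged to Cox6b2 (540), Dennd1c with Tubb4a (358) and Tango2 (322) in FAD and to Tmem125 (3100), Dysf (682) and Gmnn (599) in ND, all with peaks that overlapped a peak of the other library.

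Across the 3 libraries, 1696 genes were marked in HFD only and 127 in ND and FAD only. Actr10 led the 479 genes with an HFD peak and no ND or FAD peak within 5000 bp. Plekhh1 (193), Potegl (192), Trap1a (181) and Snrpf (180) came next. Ordered by ND score, Olfr1261, S100a4, Zfp960, Rab27b and Rhox4b led the 20 genes with ND and FAD peaks and no HFD peak within that distance. By the fixed rule the first class was led by Eppk1, Disp1, Pisd, Tenm2 and Gsk3a, and the second by Cast, Olfr1459, Tcf3, Rbm25 and Arhgef10l, of which Olfr1459 alone had no overlapping HFD peak. Because HFD enters both main comparisons, opposite differences arise by chance: a model with a detection level per library and no diet effect expected 1730 and 161 genes. HFD stood apart at 1823 genes against 1890 expected, a ratio of 0.964, where 100 simulated sets ran from 0.965 to 1.04. FAD stood apart at 1358 genes against 1289 expected, a ratio of 1.05 with simulated sets from 0.952 to 1.04. Over 161661 merged regions the same model put HFD at 0.981, below its simulated 0.993 to 1.01, and FAD at 1.04, above its simulated 0.990 to 1.02. In this model, differences from the expected numbers cancel over the 3 libraries. A low HFD ratio and a high FAD ratio are therefore not separate departures.

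**Figure D3:**
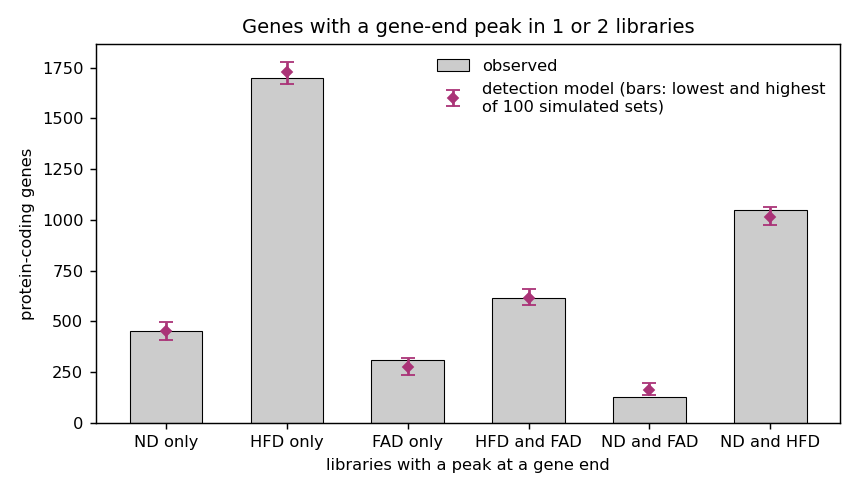
Number of protein-coding genes (y axis) with a gene-end peak in 1 or 2 of the libraries (x axis). Bars are observed counts, and diamonds with bars are the detection model with the lowest and highest of 100 simulated sets; the 1696 HFD-only genes lie within the simulated 1667 to 1777, and the 127 genes in ND and FAD only lie below the simulated 136 to 197.

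The larger number of HFD peaks was spread over all autosomes, and against ND it was absent from the sex chromosomes. HFD over ND peak numbers ran from 1.31 on chromosome 7 to 1.41 on chromosome 19, and HFD over FAD from 1.39 on chromosome 7 to 1.52 on chromosome 9. On the X the lists held 3160 ND, 3152 HFD and 2875 FAD peaks, and on the Y 2309, 1879 and 2274, which gave HFD over ND ratios of 0.998 and 0.814 and HFD over FAD ratios of 1.096 and 0.826. If the lists share a score scale, the last of these turned among stronger peaks: HFD over FAD on the Y was 1.02 at scores of 150 or more and 1.41 at 300 or more, against 1.64 and 1.89 on the autosomes. HFD over ND on the Y stayed below 1, at 0.951 for scores of 300 or more. On the X that ratio lay between 1.009 and 1.028 at cuts from 75 to 300, against 1.331 to 1.423 on the autosomes. Peaks inside gene records made up 44.2% of ND peaks (43.9 to 44.5%), 45.7% of HFD peaks (45.4 to 46.0%) and 43.2% of FAD peaks (42.9 to 43.6%), against 38.4, 38.8 and 38.4% of shuffled peaks. Gene ends took 4.04, 4.14 and 3.88%, against 3.91, 3.94 and 3.89% of shuffled peaks.

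**Figure D4:**
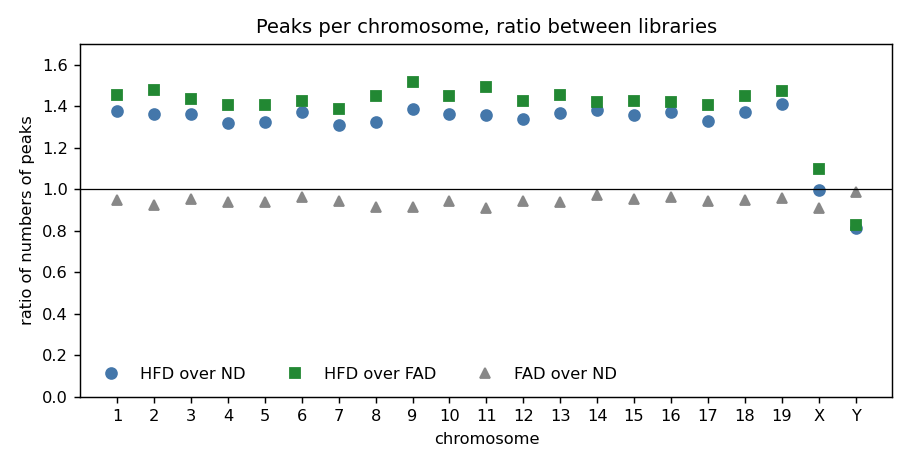
Ratio of the numbers of peaks between libraries (y axis) for each chromosome (x axis), with a line at 1. HFD over ND lies between 1.31 and 1.41 on the autosomes, at 0.998 on the X and at 0.814 on the Y.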

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

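With 1 library per diet no replicate could be left out, and no paired analysis was possible because each diet has 1 library. Depth is unknown and sets which weak regions reach the lists. The ratio of peak numbers in gene records and the members on autosomes were chosen after seeing the data, and the other alternatives were planned. CpG content, start sites of transcripts, and a detection model with absence within 5000 bp, for which the model gives no expected number, were not run. The overlap shares are given in the order ND in HFD, ND in FAD, HFD in ND, HFD in FAD, FAD in ND and FAD in HFD. They came to 84.15, 71.23, 62.68, 59.38, 76.07 and 85.15% with the 50% of peaks that scored highest, to 74.22, 71.81, 73.08, 71.97, 72.43 and 73.64% with equal-length lists, where the construction removes the difference in length, and to 74.93, 64.41, 56.31, 49.33, 68.48 and 69.8% with a reciprocal overlap of 50%. On autosomes, 4 moved, to 83.95 (ND in HFD), 61.23 (HFD in ND), 57.97 (HFD in FAD) and 85.01% (FAD in HFD). With peaks within 500 bp joined, 4 moved, to 83.81 (ND in HFD), 70.11 (ND in FAD), 62.59 (HFD in ND) and 59.42% (HFD in FAD). Gene counts are given in the order ND not HFD, ND not FAD, HFD not ND, HFD not FAD, FAD not ND and FAD not HFD. They were 364, 809, 1500, 1667, 566 and 288 with the highest-scoring 50%, and 118, 527, 779, 1009, 303 and 100 with absence within 5000 bp, where a stricter rule leaves fewer genes. Equal-length lists moved 4, to 1000 (ND not HFD), 1370 (HFD not ND), 1556 (HFD not FAD) and 867 (FAD not HFD). The observed over expected number of genes where HFD stands apart ran from 0.9642 to 0.9973 over 5 alternatives, and lay inside its simulated sets in 4 of them, as the FAD ratio did, whereas over merged regions, with 1 setting run, both lay outside. Gene-end shares of ND, HFD and FAD peaks were 3.727, 4.029 and 3.69% with the highest-scoring 50%, and 4.973, 5.246 and 4.676% with any overlap of 1 bp, where the rule itself admits more peaks. Pairs of a list and a direction beyond the central 95% of random lists were 2 with equal-length lists, inflammation (8 of 57, percentile 97.7) and DNA methylation genes (6 of 34, percentile 98.5), both HFD not ND. With the highest-scoring 50% there was 1, epididymal markers (3 of 38, percentile 99.3, FAD not HFD). With gene bodies included there was 1 such pair, lipid genes at 0 of 54, and inflammation lay at percentile 79.8. Pairs beyond the range for peak numbers in gene records were 3 with equal-length lists, against 5. Of list counts under the alternatives, 130 moved and 98 did not. Apart from those whose cause is stated, the cause was not tested.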

Other observations

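Peaks within gene records and 2000 bp on each side were counted per list, a measure chosen after the data were seen. Adipogenesis and adipokine genes held 150 peaks in HFD and 82 in FAD, a FAD over HFD ratio of 0.547 where random lists of like gene length had a median of 0.671 (percentile 0.99). Housekeeping genes held 57 and 28, a ratio of 0.491 (percentile 0.18). With equal-length lists the ratios were 0.796 (percentile 1.72) and 0.7 (percentile 0.23). Germline genes held 135 ND, 154 HFD and 121 FAD peaks. Their FAD over HFD ratio of 0.786 lay at percentile 99.2, but at percentile 83.7 with equal-length lists. Their HFD over ND ratio was 1.14 against a random median of 1.37 (percentile 0.1), and 1.13 (percentile 0.335) over the 49 members on autosomes, but with equal-length lists it lay at percentile 8.14. DNA methylation and demethylation genes held 75 ND and 122 HFD peaks, a ratio of 1.63 (percentile 98.0), which fell inside the range with equal-length lists (percentile 89.2). In total, 5 of 38 pairs of a list and a main comparison lay beyond the central 95% of random lists, where chance gives 1.9. These pairs are not independent, because both main comparisons use the HFD counts and some lists share members. Germline genes lay beyond the range in both comparisons.

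One-carbon genes held 138 peaks in ND, 198 in HFD and 146 in FAD. Their FAD over ND ratio of 1.06 lay above the random range of 0.799 to 1.04 (percentile 98.8), but with equal-length lists it was 1.09 and inside the range (percentile 94.7). Their FAD over HFD ratio was 0.737 (percentile 91.9), or 1.12 with equal-length lists (percentile 99.3). Insulin signalling genes held 211, 319 and 203 peaks, with ratios inside the random range in both main comparisons (percentiles 93.8 and 22.7). Inflammation genes held 68, 90 and 63 peaks, at percentile 49.4 for HFD over ND.

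For the weighing of the patterns below, the comparison with the detection model was planned, but the rule for reading it was written after its values were seen. The test with no other peak within 5000 bp was set before its value was seen, and the other tests were chosen after the results were seen. Genes marked in HFD only, or in ND and FAD only, are the pattern that a change with high-fat diet and its return with folic acid would give. The observed over expected number, 0.9644, shows no excess of genes where HFD stands apart. FAD stands apart more often than the model allows (1.053), which shifts the expected number. Differences from the expected numbers cancel over the 3 libraries, so the model cannot assign this departure to HFD or to FAD. That FAD excess held on autosomes (1.055) and was lost in the other 4 alternatives (1.013 to 1.044), where HFD also lay inside its own simulated sets. Over merged regions it was present as well (1.038, simulated 0.9895 to 1.016), with HFD at 0.9813 below its simulated sets. A ratio inside those sets sets no bound on changes at fewer genes, so changes in both directions stay open. A gain of methylation throughout the genome in HFD and a higher detection level of that library cannot be told apart, because each raises the peak number in the same way (1.415 times FAD) and there is 1 library per diet. Neither alone accounts for the sex chromosomes, where HFD over ND was 0.998 on the X and 0.814 on the Y. HFD over FAD was 1.096 and 0.826 there.

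Over whole lists, the longer HFD list held no more peaks than ND on the X and fewer on the Y. Weaker peaks on single-copy chromosomes are argued against, because among equal numbers of top-ranked peaks (10000, 25000, 50000 and 101532 of each list) the HFD over ND ratio on the X or Y was at most 0.8071 times the autosomal one, where weaker peaks alone would give about 1. A first version took equal percentages of each list and was replaced, because the longer list then still reaches weaker peaks. A low number of genes is argued against too for the X. Autosomal 10-Mb bins matched to the X on gene number had a median ratio of 1.334, against 1.005 for the 17 X bins. No autosomal bins were matched to the 9 Y bins. The HFD over ND ratio of the Y bins was at most 0.9786, below the lowest autosomal bin (1.116). DNA of female animals in the HFD library would raise the X ratio, which was 0.7365 times the autosomal one. The control library and settings of the peak caller, which may differ between the lists, and a biological difference between the diets stay open and were not tested.

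Peaks found in 1 library only were narrow at scores from 100 to 200. At scores of 200 to 400 this held for the 71 HFD peaks (0.474 times the median width of peaks found in all 3 libraries) but not for the 5 ND peaks (1.32) or the 3 FAD peaks (0.995). Even so, 40% of those ND peaks and 33.3% of those FAD peaks lay in the narrowest decile of their lists. At scores from 150 to 200, peaks in 1 library only had at most 0.6338 times the median width of those in all 3. This argues against lower scores as the reason. A small shift past a neighbour is argued against as well: peaks at scores from 100 to 150 with no other peak within 5000 bp were at most 0.6808 times as wide. Stacks of duplicate reads would give narrow peaks (at most 0.6964 times as wide at these scores), and so would short methylated sites, and the lists hold no reads to part them. No biological explanation was tested.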
